A study of Homo sapiens with 9 samples.

How the data were processed

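RNA was measured in MCF-7 cells, an established estrogen receptor-positive human breast cancer line. Per the labels' protocols, cells were transfected with 100 pmol of siRNA by Lipofectamine2000, a lipid reagent, and harvested 48 hours later. Total RNA was purified on silica columns and biotin-labelled cRNA was made with a TotalPrep-96 kit for Illumina bead arrays. The 9 arrays fell into 3 groups of 3: a scrambled control siRNA (siScramble), an siRNA against PABPN1 (siPABPN1) and an siRNA against ZC3H14 (siZC3H14). Groups and replicate numbers were taken from the sample titles. Nothing in the labels says whether replicates came from separate cultures, so every p-value measures only the spread between these arrays, which may be technical.

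The deposited table held 1 linear intensity per probe and array, for 47227 probes. The authors' software and background treatment are not given in the sources used here. The deposited intensities had been made to share 1 distribution before deposit: the sorted values of any array differed from those of the first by at most 0.0218 on the log2 scale, as quantile normalization leaves them. The lowest intensity was 36.6 and the median over all probes and arrays was 79.2, so dim values lie on a floor above 0, called background below. Whether any background had been subtracted cannot be told from these values. Detection calls were not used here. Because of this scaling, a change of total RNA per cell or a shift common to most genes is not visible in these values.

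Each intensity was analysed as log2(intensity + 16), with the deposited scaling kept. Folds are on that scale, which understates the change of dim genes. A probe was kept if it exceeded the pooled median of 79.2 in at least 3 of the 9 arrays, which left 26834 probes. Probe names came from the platform annotation with symbols updated through gene identifiers to the RefSeq annotation of GRCh38.p14. Of all probes, 30111 had 1 gene symbol, 8 had several and 17108 had none listed. Among kept probes, 18530 had 1 symbol and 8304 were not named. Each gene was represented by its kept probe with the highest mean, which gave 13713 genes. Of these, 3695 had more than 1 kept probe. No probe was named ZC3H14 in the annotation used, so its knockdown was not analysed here.

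Groups were compared with limma 3.58.1 in R 4.3.3, with 1 linear model of all 9 arrays and moderated variances. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and the number that also changed at least 1.5-fold was counted beside it. PABPN1 and ATP5MC1 were also compared by exact two-sided permutation of 3 arrays against 3, whose smallest possible p is 0.1. Where 1 group lay at or below the pooled median on all 3 of its arrays, the fold is given as a bound, computed with that group at the pooled median. The 30 gene lists had been fixed before the data were examined, as had the tests, the rule for naming genes and the alternatives, apart from those named below. The rule for bounds was set later. Lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, adjusted over the lists, with an estimated correlation and fry beside it. Named genes were PABPN1, ZC3H14 and ATP5MC1, the 8 largest rises and 8 largest falls of each knockdown in which all arrays lay apart from siScramble, 2 members of each called list, the 5 largest differences each way between the knockdowns and 3 genes per class of shared calls. Other names were chosen after their values were seen, as stated where they occur. Overlap of both knockdowns was set beside independent lists, and the covariance of their changes beside 100 simulations of unchanged groups that share the same controls.

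The steps were tested on simulated data of 13713 genes, of which 100 were altered 1.25-fold and 100 were altered 1.5-fold in each comparison. That is far fewer than the 6248 genes called in siPABPN1, and the adjusted threshold depends on this share. Recovery in the real comparisons may therefore differ. For siPABPN1 against siScramble, 39% of genes altered 1.25-fold and 89% of those altered 1.5-fold were recovered. The shares were 33% and 95% for siZC3H14 against siScramble, and 49% and 87% for siPABPN1 against siZC3H14. False calls were 9 of 137, 7 of 135 and 13 of 149. Each of these shares lies above the nominal 0.05, and the last is the highest. Each comes from a single simulated draw, so neither an excess of false calls nor a ranking of the comparisons is settled. Alternatives were a replicate block, quantile normalization again, array medians, no filter or a stricter one, every probe or the mean of probes, another variance model, 2 groups only, array weights, other thresholds, camera on ranks, pseudocounts of 1 and 64, and leaving out each array in turn. Cyclic loess scaling was added after seeing the data, as were array medians for the lists.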

Results

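PABPN1 and ZC3H14 are nuclear proteins that bind the poly(A) tails of RNA. The study asked how steady-state RNA levels in MCF-7 breast cancer cells change when either is depleted. Expression was measured on 9 bead arrays, 3 each for cells given siScramble, siPABPN1 and siZC3H14. All arrays shared 1 distribution of intensities, with array medians of 79.2, and the number of arrays limits the precision. Arrays of one group correlated at r = 0.994 to 0.996 across genes. Arrays of siScramble and siZC3H14 correlated at 0.990 to 0.992, and those of siScramble and siPABPN1 at 0.940 to 0.945. The first principal component held 82.8% of the variance and separated siPABPN1 from both other groups. The second held 6.58% and separated siZC3H14 from siScramble.

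**Figure D1:**
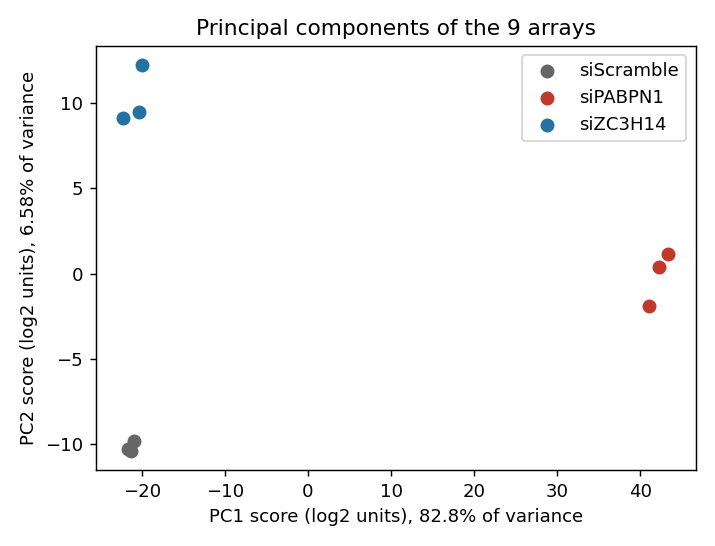
Scores of the 9 arrays on the first principal component (horizontal, 82.8% of variance) and the second (vertical, 6.58%), computed over 13713 genes in log2 units; each point is 1 array, coloured by group. The siPABPN1 arrays lie between 40.97 and 43.34 on the first component and all others between -22.25 and -20.02.

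PABPN1 was lower in each array of its own knockdown. Its intensity was 827.5 ± 61.1 in siScramble and 266.2 ± 41.5 in siPABPN1 (SD, n = 3 each), or 32.2% of control. The log2 change was -1.59 ± 0.10 (SE), with a limma adjusted p of 2.29e-10 and an exact permutation p of 0.1, the smallest 3 against 3 allows. In siZC3H14, PABPN1 stood at 981.6 ± 61.9, and that difference from siScramble did not pass the test (limma adjusted p = 0.145). The log2 difference was 0.24 with an unadjusted 95% interval of 0.04 to 0.45. All siZC3H14 arrays (912.2 to 1031) lay above all siScramble arrays (777.9 to 895.8), so a small rise is not excluded. ZC3H14 itself had no named probe, so whether its RNA fell was not analysed here and the siZC3H14 labels could not be checked this way. ATP5MC1, a subunit of the mitochondrial ATP synthase, fell in siZC3H14 from 1498 ± 46.7 to 621.1 ± 48.4 (log2 change -1.25 ± 0.08 SE, adjusted p = 2.39e-08). Both of its probes fell. In siPABPN1 it stood at 1533 ± 135, a log2 change of 0.03 with a 95% interval of -0.14 to 0.20 (adjusted p = 0.802), and the difference between the knockdowns was 1.28 on the log2 scale (adjusted p = 3.74e-10).

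**Figure D2:**
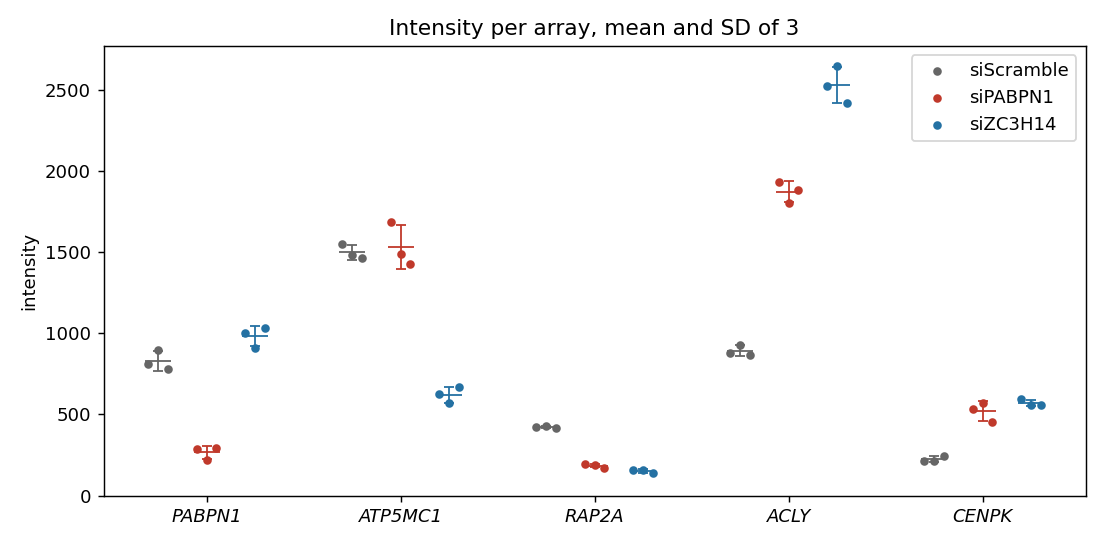
Intensity (vertical axis, linear from 0) of 5 genes per array; points are single arrays, horizontal marks the mean of 3 and bars the SD. PABPN1 falls to 266.2 in siPABPN1, ATP5MC1 falls to 621.1 in siZC3H14, and RAP2A, ACLY and CENPK move the same way in both knockdowns.

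Depletion of PABPN1 was accompanied by very large rises of interferon genes and their targets. IFNL1, a type III interferon, went from 65.4 ± 2.62 to 16100 ± 219, at least 169-fold (adjusted p = 8.18e-22). IFNB1, the type I interferon beta, went from 73.4 ± 9.20, where 2 of 3 siScramble arrays lay under the pooled median, to 13690 ± 262, and no fold is given for it. IFNL2 rose at least 123-fold, though its probe may not separate it from the near-identical IFNL3. The interferon-induced genes IFIT2, HERC5 and OASL rose 91.5-fold, 85.1-fold and 84.6-fold. Of 35 measured members of the interferon response list, 34 rose and 1 fell, with a median log2 change of 3.34 (camera adjusted p = 2.86e-46). The member that fell, IFI6, changed by -0.50 with a wide spread, at 916.6 ± 308 against 1262 ± 161, and was named after its value was seen; with cyclic loess scaling no member fell.

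Inflammatory and immediate early genes rose with them. Of 28 listed inflammatory and NF-kB targets 19 were measured, and all 19 rose (adjusted p = 3.43e-23). The filter favours genes that rose: 6 of the 19 exceeded the pooled median in siPABPN1 arrays only, and without a filter 19 of 26 rose and 0 fell. In siScramble 10 of the 19 lay at or below the pooled median on all arrays, and with these at their bounds the median log2 change of the list was 1.8. Among the 19 were the chemokines CCL5, 71.9-fold from 251.2 ± 34.0 to 19100 ± 365, and CXCL8, at least 62.6-fold. Of 29 immediate early genes, which respond within minutes to many stimuli, 27 rose and none fell (adjusted p = 3.09e-22). The transcription factors EGR1 and KLF4 rose 17.7-fold and 16.99-fold, and KLF4 varied widely between arrays, at 5726 ± 1980. Blood and endothelial markers, genes typical of other cells, did not pass as a list (adjusted p = 0.134). Some had signal in siScramble, such as HBA1 at 247. Of the 15 measured, 3 rose and 1 fell. CD14 and CD68, myeloid markers chosen after their values were seen, rose by 0.90 and 1.01 on the log2 scale, to intensities of 175.6 and 471.6. CD8A, chosen in the same way, was lower on both kept probes, from 154 to 86.9 and from 132 to 72.5.

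**Figure D3:**
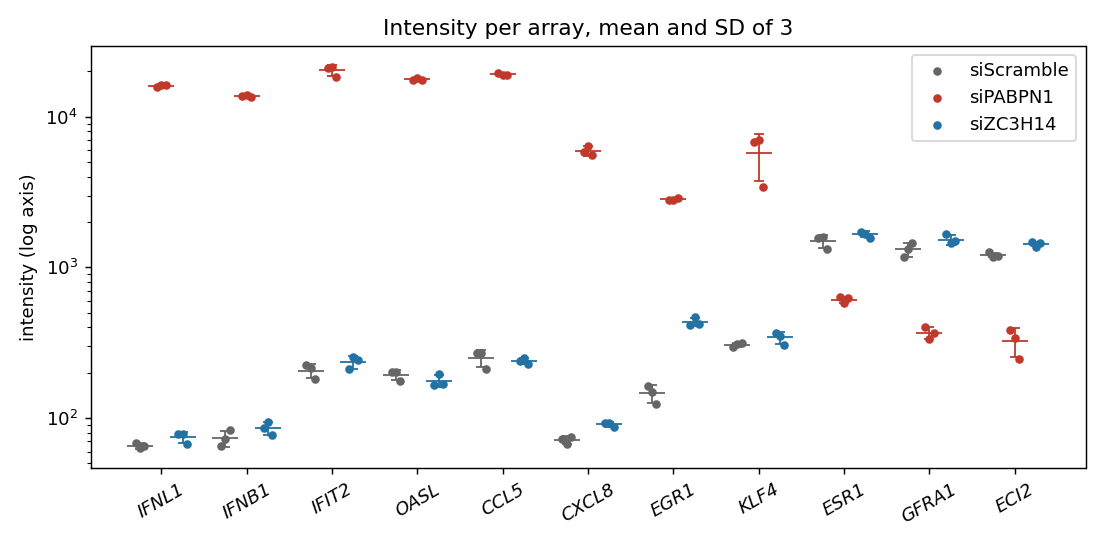
Intensity (vertical, log axis) of 11 named genes per array; points are single arrays, horizontal marks the mean of 3 and bars the SD. In siPABPN1 the interferon, chemokine and immediate early genes are far above siScramble and siZC3H14, for example IFNL1 at 16100 against 65.39 and 74.84, while ESR1, GFRA1 and ECI2 are lower.

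Other lists that rose in siPABPN1 were smaller in size. Of 40 replication-dependent histone genes, whose mRNAs normally end without a poly(A) tail, 16 rose and 2 fell (adjusted p = 8.37e-05), and 21 rose and 0 fell under cyclic loess. The histone genes H2AC18 and H2AC20 rose by 2.07 and 1.54 on the log2 scale. Near-identical histone copies can share a probe, so single members are uncertain. Array labelling of this kind primes on poly(A) with oligo(dT), so more tailed histone copies cannot be told apart from more histone RNA. Unfolded protein response and ATF4 targets were called (adjusted p = 0.0268) with 10 of 25 higher and 6 lower, but not with an estimated correlation (adjusted p = 0.246) or on ranks. The transcription factors ATF3, up 16.6-fold, and CEBPB, up 5.32-fold, led that list and also respond to inflammatory signals. Zinc finger CCCH proteins were called (adjusted p = 0.0066) with 8 of 20 higher and 3 lower, again not with an estimated correlation (adjusted p = 0.0698) or on ranks. Its leading members were ZFP36 and ZFP36L2, up 10.1-fold and 5.44-fold, which promote decay of AU-rich mRNAs.

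Estrogen-responsive and sterol genes fell in siPABPN1. Of 28 estrogen-responsive genes, 20 fell and 2 rose (adjusted p = 2.47e-05, and adjusted p = 0.192 with an estimated correlation). ESR1, the estrogen receptor alpha, fell from 1495 ± 155 to 612.3 ± 28.5, 2.40-fold, and the ubiquitin ligase SIAH2 fell 2.30-fold. Cholesterol synthesis genes fell in 16 of 22 and rose in 1 (adjusted p = 0.00083, and adjusted p = 0.203 with an estimated correlation), including FASN, which makes fatty acids, by 0.85 and MSMO1 by 0.62 on the log2 scale. Respiratory chain genes fell in 25 of 55 and rose in 1 (adjusted p = 0.00958, and adjusted p = 0.0576 with an estimated correlation), with SDHC and NDUFV1 lower by a log2 change of -0.54 and -0.51. Cytosolic ribosomal proteins fell in 26 of 66 and rose in 1 (adjusted p = 0.0327, and adjusted p = 0.0732 with an estimated correlation), with RPS23 and RPL22 at -0.73 and -0.66. These last lists depended on the scaling: under cyclic loess 9 respiratory genes fell and 5 rose, while 11 ribosomal proteins fell and 8 rose with a median of 0.04 instead of -0.11, and neither list passed. In the deposited scaling, members called against their list, named after their values were seen, were CRELD2, PDIA4, PSAT1, PHGDH, SLC7A5 and EDEM1 of the unfolded protein response list (lower), H2AC11 and H2BC5 (lower), ZC3H8, ZC3HC1 and MBNL3 (lower), XBP1 and FOXA1 (higher), HSD17B7 (higher), COX7B (higher) and RPL36 (higher). Of these HSD17B7 changed by 1.31, PDIA4 by -0.81 and FOXA1 by 0.69. The interferon, inflammatory, immediate early and histone calls held with an estimated correlation, at adjusted p = 0.0181, 0.00324, 0.00113 and 0.0495.

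The largest single falls outside PABPN1 were ECI2, a peroxisomal enzyme of fatty acid oxidation, 3.67-fold from 1209 ± 44.2 to 323.2 ± 70.0, and GFRA1, a co-receptor of GDNF, 3.47-fold. BRI3BP fell 3.33-fold on its brightest probe, and 2 of its 4 probes were called in that direction. SELENOT, a selenoprotein of the endoplasmic reticulum, UBL3, the ESCRT-III subunit CHMP3, and ACO1, the iron-responsive aconitase, fell 2.86-fold, 2.79-fold, 2.77-fold and 2.74-fold. For 6 genes, probes changed at least 1.5-fold in opposite directions. They were ABCG1, BLOC1S6, FAM177A1, PPA2, SLC25A24 and ZMAT3, and no direction is given for them.

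In total 6248 of 13713 genes (45.6%) changed in siPABPN1, 2435 higher and 3813 lower, and 1733 changed at least 1.5-fold, 1001 higher and 732 lower. The 3 arrays lay wholly apart from siScramble for 52.7% of genes, where chance gives 10%. The balance of small changes depended on the scaling: with cyclic loess 3218 genes were higher and 2598 lower, or 55.3% higher against 39.0% in the deposited scaling. In the deposited scaling the median log2 change went from -0.000277 in the dimmest of 5 equal bins of genes to -0.14 in the brightest.

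The other 20 lists did not pass in siPABPN1 as tested here, and the balance of many depended on the scaling. Some passed under camera alternatives. Under cyclic loess the proteasome (adjusted p = 0.0112), snoRNA host and nonsense-mediated decay lists (both 0.0388) passed as higher. ATP synthase, G1/S and mitosis genes passed as lower without a filter (0.0158, 0.0251 and 0.0251) and with the mean of probes (0.0136, 0.0374 and 0.0499), and ATP synthase also on ranks (0.0439). SnoRNA hosts also passed as higher with the mean of probes (0.0231), without siScramble replicate 1 (0.0486) and without siPABPN1 replicate 3 (0.0469). Counts that rose and fell are given in the deposited scaling and then under cyclic loess, with the adjusted p of the deposited scaling in brackets. They were 5 and 20 of 42 G1/S genes, then 11 and 13 (0.0838), 3 and 14 of 38 mitosis genes, then 5 and 6 (0.0952), and 1 and 9 of 18 ATP synthase subunits, then 1 and 4 (0.0628). SnoRNA hosts and long noncoding RNAs gave 13 and 5 of 27, then 15 and 4 (0.0628), and hypoxia and glycolysis genes 7 and 17 of 32, then 8 and 16 (0.116). Among RNA-processing lists, export genes gave 2 and 7 of 27, then 8 and 1 (0.862), SR proteins and hnRNPs 8 and 11 of 37, then 11 and 5 (0.872), and cleavage and polyadenylation factors 6 and 9 of 21, then 6 and 6 (0.862). Poly(A) binding and deadenylation genes gave 10 and 8 of 29, then 13 and 5 (0.161), exosome genes 8 and 4 of 21, then 9 and 2 (0.402), and nonsense-mediated decay factors 6 and 1 of 15, then 7 and 0 (0.112). MYC targets gave 6 and 12 of 36, then 8 and 4 (0.5), proteasome subunits 5 and 2 of 27, then 13 and 1 (0.217), and p53 targets 7 and 7 of 25, then 10 and 3 (0.162). Heat shock genes gave 5 and 6 of 20, then 7 and 4 (0.870), apoptosis regulators 13 and 8 of 31 in both scalings (0.148), and lysosome and autophagy genes 9 and 7 of 32, then 13 and 3 (0.242). Luminal markers gave 4 and 10 of 22, then 8 and 8 (0.545), and basal and mesenchymal markers 7 and 4 of 17, then 7 and 3 (0.242). Adjusted over the list alone, the counts were the same for the interferon, inflammatory, immediate early, histone, estrogen and respiratory lists, and 18 cholesterol genes fell.

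**Figure D4:**
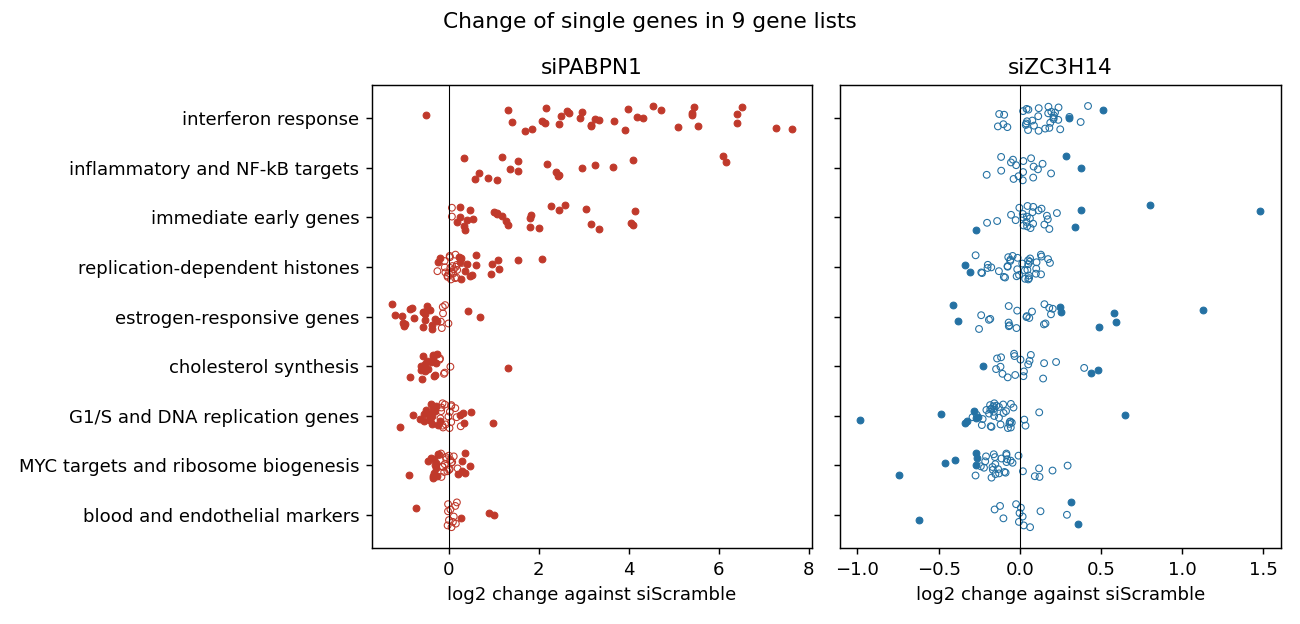
Log2 change against siScramble (horizontal; the 2 panels have different ranges) of each measured gene of 9 lists in siPABPN1 (left) and siZC3H14 (right); filled points passed an adjusted p of 0.05 and open points did not, and the vertical spread within a list has no meaning. In siPABPN1 34 of 35 interferon genes lie right of 0 and are filled, and in siZC3H14 2 are.

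In siZC3H14, where loss of ZC3H14 was not measured, fewer genes differed from siScramble. ACLY, which makes acetyl-CoA for lipid synthesis, rose 2.80-fold from 892.5 ± 33.6 to 2530 ± 112 (adjusted p = 1.26e-09), and EGR1 rose 2.79-fold from 146.1 ± 19.8 to 435.0 ± 28.5 (adjusted p = 6.24e-09). CENPK, a kinetochore protein, and SPRING1, a regulator of sterol signalling, rose 2.44-fold and 2.29-fold. LPP, the transcription factor MYB, PLEKHA1 and the small nucleolar RNA SNORA12 rose between 2.14-fold and 2.20-fold. VMA21, an assembly factor of the vacuolar proton pump, fell 2.66-fold from 1076 ± 71.1 to 394.2 ± 14.7, and the small GTPase RAP2A fell 2.60-fold. MAPK1IP1L, SSR1, PURB, HMGN4 and the tight junction protein CLDN12 fell between 2.25-fold and 2.46-fold, beside ATP5MC1 at 2.38-fold. Except for MYB and ATP5MC1, each of these genes was also called in siPABPN1 in the same direction, against the same siScramble arrays. In siPABPN1, ACLY changed by 1.055, VMA21 by -0.46 and CLDN12 by -0.77 on the log2 scale, while MYB changed by -0.43. Since 45.6% of all genes were called in siPABPN1, a shared call alone says little. Some of these changes were much larger in siZC3H14 than in siPABPN1, such as SPRING1 (1.19 against 0.29), MAPK1IP1L (-1.30 against -0.355) and HMGN4 (-1.18 against -0.44). Others were of similar size, such as CENPK (1.29 against 1.15) and SSR1 (-1.24 against -1.11).

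In siZC3H14 6 lists passed with the preset correlation, and none with an estimated one. G1/S and DNA replication genes fell in 7 of 42 and rose in 1 (adjusted p = 5.48e-06, and 0.105 estimated), led by RRM2, a subunit of ribonucleotide reductase, down 1.98-fold, and by the clamp loader RFC3, down 1.40-fold. MYC targets and ribosome biogenesis genes fell in 6 of 36 (adjusted p = 8.73e-05, and adjusted p = 0.0567 with an estimated correlation), including ODC1, down 1.67-fold, and BOP1, down 1.38-fold. Interferon genes were called higher (adjusted p = 0.00182, and adjusted p = 0.623 with an estimated correlation), with 2 of 35 past the test, MX1 at 1.43-fold and IFIH1 at 1.24-fold. The list call ended with fry (adjusted p = 0.171) and without siZC3H14 replicate 2 (adjusted p = 0.156), and that of IFIH1 without any 1 of 4 arrays, siScramble replicates 2 and 3 and siZC3H14 replicates 2 and 3. SnoRNA hosts and long noncoding RNAs fell in 6 of 27 (adjusted p = 0.0103, and adjusted p = 0.105 with an estimated correlation), including SNHG9 and SNHG7. SNHG7 was called on 1 of its 3 probes and did not pass with their mean, nor without siScramble replicate 1 or siZC3H14 replicate 3. Immediate early genes rose in 4 of 29 and fell in 1 (adjusted p = 0.0161, and adjusted p = 0.105 with an estimated correlation), with FOS at 1.75-fold beside EGR1, and the call ended on ranks. Respiratory chain genes fell in 5 of 55 (adjusted p = 0.0342, and adjusted p = 0.105 with an estimated correlation), with NDUFA11 at 1.70-fold and NDUFA8 at 1.43-fold, and the call ended under cyclic loess, on ranks, and without siScramble replicate 2 (adjusted p = 0.0705) or siZC3H14 replicate 3 (adjusted p = 0.0759). The G1/S gene that rose was RFC5 and the immediate early gene that fell was MYC, both named after their values were seen; under cyclic loess no immediate early gene fell. The other 24 lists had adjusted p of 0.159 or more, and without siScramble replicate 1 the unfolded protein response list passed as lower (adjusted p = 0.0413). Adjusted over the list alone, 11 G1/S genes and 10 MYC targets fell.

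In total 1258 of 13713 genes (9.17%) changed in siZC3H14, 663 higher and 595 lower, and 127 changed at least 1.5-fold, 72 higher and 55 lower. The arrays lay apart for 28.1% of genes, where chance gives 10%. Without siScramble replicate 1 the count was 818, with 375 lower.

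Between the knockdowns, siPABPN1 and siZC3H14 differed in 6150 genes, 2478 higher and 3672 lower in siPABPN1, and 1793 differed at least 1.5-fold. Here too cyclic loess changed the balance, to 3210 higher and 2665 lower. IFNL1 was at least 169-fold and IFNL2 at least 123-fold higher in siPABPN1, OASL 92.4-fold and HERC5 82.8-fold. IFNB1 stood at 13690 ± 262 against 85.3 ± 8.43 in siZC3H14, close to background, so no fold is given. AFAP1L2 was 4.35-fold lower in siPABPN1 than in siZC3H14, ECI2 4.33-fold, GFRA1 4.03-fold, PABPN1 3.56-fold and EEIG2 3.18-fold. Of the lists, 10 differed. Interferon (1.71e-44), inflammatory (2.28e-22), immediate early (1.59e-20) and histone genes (1.05e-05) were higher in siPABPN1 by camera adjusted p and held with an estimated correlation. Unfolded protein response (0.00183), snoRNA host (0.00841), zinc finger CCCH (0.0116) and nonsense-mediated decay genes (0.0293) were higher but had adjusted p of 0.15, 0.0971, 0.0971 and 0.123 with an estimated correlation. Estrogen-responsive genes (6.63e-06) and cholesterol genes (0.000441) were lower, with adjusted p of 0.15 and 0.163 when the correlation was estimated. On ranks the zinc finger CCCH list did not pass. Proteasome subunits passed as higher in siPABPN1 under cyclic loess (adjusted p = 0.00124), without a filter (0.0315), with the mean of probes (0.0452), on ranks (0.0176) and without siScramble replicate 3 (0.0459). Ribosomal proteins passed as lower without a filter (0.0103), with the mean of probes (0.00527) and without siZC3H14 replicate 3 (0.0464), and MYC targets as higher under cyclic loess (0.0409). Of 27 snoRNA hosts, 13 were higher and 4 lower in siPABPN1. SNHG9 stood at 4990 ± 160 in siPABPN1, 2023 ± 19.8 in siScramble and 1526 ± 62.6 in siZC3H14.

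Some genes moved in both knockdowns. EGR1, CENPK and SNORA12 were higher in both, CENPK by 1.15 in siPABPN1 and 1.29 in siZC3H14 on the log2 scale. RAP2A, SSR1 and HACD2, an enzyme of very long chain fatty acid synthesis, were lower in both, RAP2A by -1.13 and -1.38. B4GALT5, a galactosyltransferase, rose by 3.40 in siPABPN1 and fell by 1.06 in siZC3H14, and the metallothionein MT2A rose by 2.30 and fell by 0.61; IFI27L1 went the same ways. AFAP1L2, TMT1A and the heme-binding protein HEBP1 fell in siPABPN1 and rose in siZC3H14, AFAP1L2 by -1.39 and 0.73. In all, 227 genes were higher in both and 338 lower in both, where independent lists of these sizes would share 117.7 and 165.4. In opposite directions there were 84 genes higher in siPABPN1 and lower in siZC3H14 (105.7 for independent lists) and 202 the other way (184.4). Independent lists treat all genes alike, but calls were rarer among dim genes in both knockdowns. In the dimmest of 5 bins siPABPN1 had 190 calls higher and 134 lower, against 564 and 1157 in the brightest. For siZC3H14 the counts were 16 and 12, against 167 and 193. The expected counts are therefore too low, and the size of any excess was not determined. Without siScramble replicate 1 the calls shared in the same direction fell from 565 to 354. Those in opposite directions fell from 286 to 160, and to 164, 179 and 173 without siScramble replicate 2, siScramble replicate 3 or siZC3H14 replicate 1. These 851 genes were 67.6% of the siZC3H14 calls. Across genes, which are not independent replicates, the log2 changes correlated at r = 0.179. Unchanged groups sharing the controls gave a median of 0.524 and a range of -0.303 to 0.906. These r values are not alike, because siPABPN1 changes far exceeded the spread between arrays, which by itself lowers r. Root mean square log2 differences were 0.551 to 0.577 between siScramble and siPABPN1 arrays and 0.149 to 0.158 among siScramble arrays. The covariance was 0.0172 against a simulated 0.00422 (range -0.00142 to 0.0101), a difference of 0.013. The 3 controls were not split between the knockdowns, so part of the overlap may come from sharing them.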

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

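All tests of explanations here were chosen after the result was seen, except the counts of other splits of the arrays.

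Of 8304 kept probes that the annotation used does not name, 269 were at least 1.5-fold higher and 165 at least 1.5-fold lower in siPABPN1 than in siScramble by limma at an adjusted p under 0.05. They lie outside the comparisons of genes and so were looked at separately. Probe ILMN_2043126 rose from 60.1 ± 5.51 to 3414 ± 55.1 and ILMN_2412880 from 45.7 ± 3.91 to 1444 ± 89.1, while ILMN_1775759 and ILMN_1671486 changed by -1.35 and -1.28 on the log2 scale. In siZC3H14, 7 such probes were higher and 8 lower. Probe ILMN_2335669 fell from 465.2 ± 26.0 to 105.5 ± 10.9 and ILMN_1714805 from 239.5 ± 10.8 to 78.2 ± 1.21, and ILMN_1775943 and ILMN_1797964 rose by 0.83 and 0.78. The genes of these probes were not analysed here.

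The first pattern weighed is the rise of interferon and inflammatory genes in siPABPN1. Blood cells in the cultures would bring their own transcripts, but the 15 measured blood and endothelial markers had a median log2 change of 0.0932 (SD 0.397) against 3.34 for the interferon list, and none of them is in another list. The myeloid markers CD14 and CD68 did rise, from 86.2 to 176 and from 227 to 472, while probes for LYZ and TYROBP, abundant in myeloid cells, stayed at background (71.7 or less) in both groups, and 7 of the 15 were above the pooled median on all siScramble arrays. Transfection as such is not the whole cause, since siZC3H14 cells were transfected alike and the interferon list was 3.13 higher in siPABPN1 than there. An effect of the siPABPN1 sequence apart from loss of PABPN1, such as sensing of that duplex, cannot be told apart from loss of PABPN1, because 1 group received an siRNA against PABPN1.

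The second pattern is the excess of small falls among bright genes in siPABPN1. Quantile normalization could produce a shift of this kind. The rises of at least 1.5-fold (1486 probes) were imposed on the siScramble arrays, which were normalized again. Genes without such a rise shifted by -0.16 in the brightest of 5 bins, against a measured median of -0.174. In the dimmest bin the shift was -0.00527 against -0.00256. The falls were not imposed, and the measured medians left out genes with such a rise but kept those that fell. Over all genes the measured median of the brightest bin was -0.135, so the close match is partly built in. A general fall of abundant mRNAs cannot be told apart from an effect of normalization, because the deposited arrays share 1 distribution to within 0.0218. Falls of over 1.5-fold exceed the simulated median shift.

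The third pattern is a rise of small nuclear RNAs in siPABPN1, described among the other observations: 12 of 13 rose, with a median of 2.42, though the 13 were grouped after their rises were seen and include near-identical U1 and U4 genes. More short RNA carried through extraction would raise snoRNAs too, yet the 91 snoRNAs at least as bright as the dimmest snRNA had a median of 0.0839 (SD 0.51) at a median length of 114 nt against 145 nt, and the 35 above 2 times the pooled median had a median of 0.0691 (SD 0.684), of which 12 rose and 6 fell. Some other short RNAs go with that explanation, namely RNA5S9 at 2.01, RPPH1 at 2.27, SNORD3D at 3.18 and all 4 Y RNAs. Others do not. The vault RNAs VTRNA1-2, VTRNA1-1 and VTRNA2-1 (88 to 108 nt) changed by 0.21, 0.19 and 0.04, though VTRNA1-2 and VTRNA2-1 were dim. The long RNA18SN5 (1869 nt) and RNA28SN5 (5070 nt) rose by 0.84 and 0.80. With rows on both sides, the snoRNAs argue against that explanation only as the whole cause. Array labelling of this kind primes on poly(A) with oligo(dT), and all 9 arrays were labelled with the same kit, so more tailed copies per RNA cannot be told apart from more RNA. Loss of PABPN1 and the interferon state are both open as biological explanations and were not tested.

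Other splits of the 6 arrays of each comparison were too few (10) for a share under 0.05. The real split of siPABPN1 and siScramble called 6248 genes, that of siZC3H14 and siScramble 1258 and that of siPABPN1 and siZC3H14 6150. Each was the only 1 of its 10 splits to call as many, and the highest of the others called 0. Those other splits mix arrays of both groups, so the differences between groups widen their spread and few calls could be made. The 0 therefore gives no rate of false calls.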

How the results depend on the processing

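The cyclic loess scaling, and array medians for the lists, were chosen after seeing the data. No named gene or called list passed its test in the other direction under any alternative, but cyclic loess turned the balance of the siPABPN1 calls to 3218 higher and 2598 lower, and that of the difference to 3210 and 2665. It also moved the median of the ribosomal proteins from -0.106 to 0.0386 and the counts of export genes from 2 higher and 7 lower to 8 and 1. Requiring 1.5-fold gave the same counts with an adjusted or an unadjusted p: 1733 genes in siPABPN1 (1001 higher, 732 lower), 127 in siZC3H14 (72 and 55), 1793 between the knockdowns (933 and 860), and 30 genes changed in both in the same direction and 5 in opposite ones, fewer by construction. With an estimated correlation 4, 0 and 4 lists passed in siPABPN1, siZC3H14 and their difference, and with fry, which does not compare a list with other genes, 27 and 26 passed in siPABPN1 and the difference, while the interferon call in siZC3H14 ended (adjusted p = 0.171). Camera on ranks ended 5 of the 26 list calls, those of the unfolded protein response and zinc finger lists in siPABPN1, the respiratory and immediate early lists in siZC3H14 and the zinc finger list in the difference. Lists were also gained: without a filter 13 and 12 passed in siPABPN1 and the difference, with the mean of probes 14 and 12, and under cyclic loess 11 and 12.

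The replicate block gave 6229, 1243 and 6145 genes. The numbers gave no clear sign of pairing. Over 9 same-numbered pairs the deviations correlated between -0.091 and 0.141, with 2 pairs above 0.1, and 4 of 9 arrays correlated best with their own number. A weak effect shared by arrays of the same number is not excluded. Cyclic loess gave 5816 genes in siPABPN1 (55.3% higher against 39.0%), of which 5021 were called in the deposited scaling, and 5875 between the knockdowns (54.6% against 40.3%).

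Leaving out 1 array in turn gave 5635 to 6238 genes in siPABPN1 (2228 to 2439 higher, 3378 to 3799 lower), 5470 to 6151 between the knockdowns (2236 to 2479, 3234 to 3674), and 818 to 1400 in siZC3H14 (443 to 747, 375 to 653), lowest without siScramble replicate 1. Shared calls ran from 354 to 607 in the same direction and 160 to 296 in opposite ones, also lowest without that array, and r from 0.153 to 0.205. PABPN1 ran from -1.66 to -1.46. Lists numbered 10 to 11, 5 to 7 and 10 to 11. The causes were not tested. Over all alternatives, 1711 of 1722 values of named genes and 438 of 468 values of called lists kept their side of the threshold. With background near the median intensity of 79.2, changes of dim genes are limited by signal over background.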

Other observations

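Several noncoding RNAs, chosen after the values were seen and classed by RefSeq biotype, rose in siPABPN1. RN7SK, which restrains transcription elongation, went from 138.3 to 3672, a log2 change of 4.58 ± 0.08 (SE). The spliceosomal RNAs RNU4-2, RNU1-1 and RNU6-1 changed by 3.76, 2.57 and 1.96. The U1 genes are near-identical, so their probes do not count as separate signals. RPPH1, the RNA of RNase P, changed by 2.27 and RNA5S9, a 5S ribosomal RNA, by 2.01. The U3 RNAs SNORD3A, SNORD3C and SNORD3D changed by 1.91, 1.65 and 3.18, and all 4 Y RNAs rose, with a median of 0.614. SNORD3C stood at 81.2 in siScramble, near the pooled median of 79.2, so the size of its change is uncertain. Smaller rises were those of TERC, the telomerase RNA, at 0.55 and RN7SL1, the signal recognition particle RNA, at 0.43. Both are limited by their siScramble levels, TERC at 81.1 near the pooled median of 79.2, and RN7SL1 at 12920 with little room to rise. The vault RNAs VTRNA1-2, VTRNA1-1 and VTRNA2-1 changed by 0.21, 0.19 and 0.04, of which the first passed the test. In siScramble VTRNA1-2 and VTRNA2-1 had means of 74.15 and 69.7, below the pooled median of 79.2, so their changes are uncertain. SNAR-A1, an snRNA by that biotype, did not pass the test, at 0.08. It stood at 15630 in siScramble, where the highest value of an array is 22167, so it had little room to rise. The long ribosomal RNAs RNA18SN5 and RNA28SN5 rose by 0.84 and 0.80.

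Of 153 snoRNAs 42 rose and 8 fell in siPABPN1, with a median of 0.077, and of 74 microRNA genes 6 rose and 6 fell. In siZC3H14 2 of the 13 snRNAs rose and 2 fell, with a median of 0.173, among them RNU4-2 at 0.38 and RNU4ATAC at -0.44.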
